A study of Mus musculus with 8 samples.

How the data were processed

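Liver sinusoidal endothelial cells are the fenestrated cells that line the liver's capillaries. Per the labels, they were sorted from female Balb/c mice by flow cytometry as CD45-dim, STAB2-high, CD146-high cells, 5 h after an intravenous injection of iron citrate (150 µg) or of 0.05 M citrate buffer. RNA was extracted with a phenol-based reagent with glycogen as carrier, and libraries were made with an amplicon kit for the mouse transcriptome (Ion AmpliSeq), per the labels' protocols. In this assay each gene is read through 1 short amplicon, so a value describes the amplified part of a transcript and not its whole length. The series' design text speaks of 5 against 5 samples. Here 4 libraries per group were used, and the others were not analysed here.

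The authors deposited whole-number read counts for 23930 RefSeq targets, 1 file per library. The counts were made with HTSeq 0.6.0, and DESeq2 1.18.1 is also named, per the submitters' processing notes. The aligner, the genome build and any read filter are not given in the sources used here, so no coordinates are printed. HTSeq's summary lines for reads without a target, of low quality or not aligned made up 2.15% to 4.60% of the reads in a file and were left out of library sizes and tests. Symbols were matched to the RefSeq accessions with the reference tables, 18128 by the versioned accession, 4324 without the version and 110 through a second RefSeq table. The 1368 targets with no match kept their accession. Targets of near-identical family members can share reads, and their values are uncertain to that extent.

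Counts on targets came to between 7969520 and 11314659 per library. Amplicon reads carry no molecular identifiers, so intervals around shares cover counting error only. The labels name 1 mouse per library and say nothing more on how independent the animals were, so p-values measure the spread between these samples.

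Iron citrate was compared with citrate buffer with edgeR 4.0.16 in R 4.3.3. Targets with low counts were removed with filterByExpr, which left 14601. Libraries were scaled with TMM factors, and a quasi-likelihood F-test with robust dispersion was run. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. CPM were computed with library sizes scaled by the TMM factors, except over gene families, where the unscaled counts on targets were used. Standard errors of log2 fold changes were derived from the F statistic. Before the data were examined, 34 gene lists were fixed, 21 of response genes and 13 of cell type markers. Each was tested against all other tested genes with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry, a rotation test of the list alone, were run beside it.

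The genes named in the text were set by a rule fixed before the data were examined. It took 12 genes from the study's question and its sort, which are *Bmp6*, *Bmp2*, *Ets1*, *Nfe2l2*, *Mapk14*, *Tfrc*, *Slc40a1*, *Hmox1*, *Nqo1*, *Stab2*, *Mcam* and *Ptprc*. It added up to 10 called genes per direction with the largest change, a mean CPM of at least 5 and groups that did not overlap. From each response list it took up to 4 called members, or the first 2 measured ones where fewer than 2 were called, and from each cell type list the 2 most abundant members and any called one. Genes outside this rule are said to be so where they are named.

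The alternatives fixed beforehand were relative log expression, upper-quartile or no scaling factors, DESeq2 1.42.0, limma-voom with sample weights, no low-count filter, a mean CPM of at least 5, the replicate number as a block, a test against a 1.2-fold change, each library left out in turn, and lists without shared members. A fit without citrate buffer replicates 1 and 2, and a fit with the signal on gene families silent in liver as a covariate, were added after the data were seen. Pairs of libraries within a group were checked for duplicates by their chi-square per degree of freedom. It was at least 8.3, so each of these pairs differed by more than sampling noise. Pairs across groups were not checked.

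The edgeR step was tested on counts simulated for this comparison over 14473 genes, of which 200 were changed. It called 32 of 100 genes changed 2-fold, 87 of 100 changed 4-fold and 8 of 14273 unchanged genes, and 0 of the 200 changed genes were called in the wrong direction. The same simulation gave 52, 92 and 49 calls with DESeq2 and 26, 87 and 8 with limma-voom. Camera called 0 of 200 unchanged lists. These lists were drawn at random from genes simulated independently, so this does not cover lists whose members vary together. Tables and plots were made with Python 3 and pandas.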

Results

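The transcriptome of sorted liver sinusoidal endothelial cells was measured 5 h after mice received iron citrate or citrate buffer into a vein, with 4 libraries per group. These cells are the main hepatic source of BMP6, the ligand that sets hepcidin, the hormone of iron balance. Counts on targets were 9150970, 11314047, 11314659 and 7969520 in citrate buffer replicates 1 to 4 and 10512417, 9010874, 10141001 and 11061968 in iron citrate replicates 1 to 4. Between 17830 and 20020 of the 23930 targets had at least 1 count. The markers of the sort were abundant, with *Stab2* at 1086 ± 154 CPM (SD, n = 4) after buffer and 977 ± 131 CPM after iron. *Clec4g*, a lectin of sinusoidal endothelium, stood at 9476 ± 1996 and 10020 ± 966 CPM.

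Citrate buffer replicate 1 stood apart from the other libraries. Its median correlation with its own group was 0.84, against 0.96 to 0.98 for the other 7 libraries, and the first principal component, with 71.1% of the variance, separated it and, less far, citrate buffer replicate 2 from the rest. The second component, with 9.1%, separated the groups. Olfactory, vomeronasal type 1 and bitter taste receptors and keratin-associated proteins, families with an intronless coding sequence that liver is not known to express, drew 2.42% of the counts in citrate buffer replicate 1 and 0.98% in citrate buffer replicate 2. In the other 6 libraries they drew 0.30% to 0.61%. Over 138 targets of families whose coding sequence is split by introns, the mean was 0.09 CPM in citrate buffer replicate 1, against 18.8 CPM over the 1286 intronless targets.

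**Figure D1:**
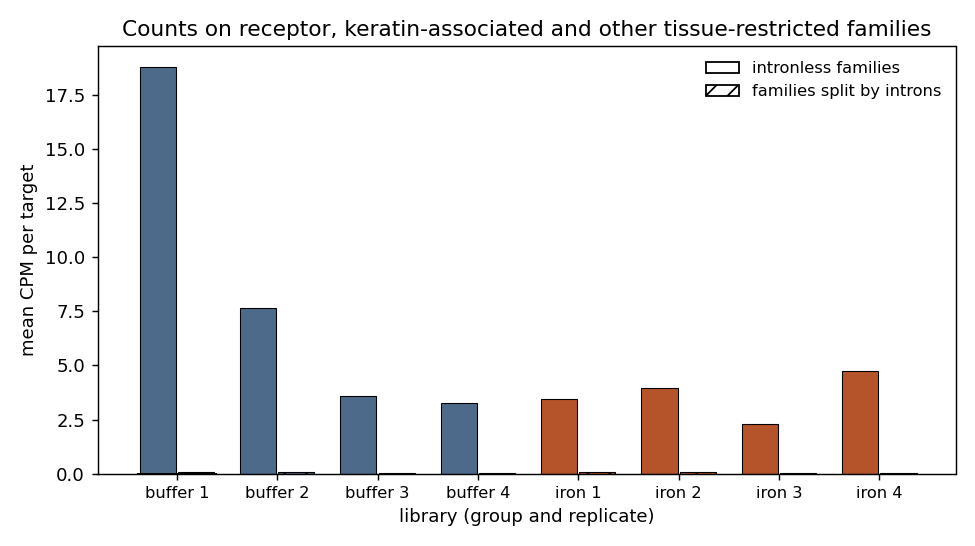
Bars give the mean CPM per target in each library for tissue-restricted families with an intronless coding sequence (plain) and for families split by introns (hatched), citrate buffer in blue and iron citrate in orange. The intronless families stood at 18.8 CPM in citrate buffer replicate 1, at 7.64 CPM in replicate 2 and between 2.29 and 4.75 CPM in the other libraries.

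The series asks how iron raises *Bmp6* mRNA in these cells and what part NRF2, the p38 kinase and ETS1 have in it. *Bmp6* rose 5.15-fold after iron citrate, from 323 ± 184 CPM to 1661 ± 108 CPM (SD, n = 4 each), a log2 fold change of 2.36 with an SE of 0.42 and an edgeR adjusted p of 0.0423. The lowest iron citrate library, at 1582 CPM, lay above the highest buffer library, at 536 CPM, and citrate buffer replicate 1 had the lowest value, 97.4 CPM. *Bmp2*, the other BMP ligand that sinusoidal endothelium makes for hepcidin control, stood at 1763 ± 819 CPM after buffer and 2389 ± 182 CPM after iron (log2 fold change 0.44, SE 0.36, adjusted p = 0.507). Without citrate buffer replicate 1 the *Bmp6* log2 fold change was 2.06 with an SE of 0.19 (adjusted p = 1.51e-05), and leaving out any other library except citrate buffer replicate 4 gave adjusted p-values of 0.13 to 0.219 at log2 fold changes of 2.30 to 2.44. The *Bmp6* call was also lost with the replicate block.

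Across the 14601 tested targets, 77 genes rose and 4 fell after iron citrate, and 59 of the former and 3 of the latter changed at least 2-fold. In all 81, the 4 iron citrate values lay to 1 side of the 4 buffer values, against 8.6% of all tested genes and 2.86% by chance. The genes were called on these same values, so this is no separate support for the calls. At an unadjusted p under 0.05 in the same edgeR test, 959 genes were higher and 1168 lower. The excess of rises among the called genes did not extend to this wider set. Of the 10 largest rises among genes with a mean CPM of at least 5, 6 were in NRF2 targets. *Hmox1*, the haem oxygenase that frees iron from haem, rose 36.5-fold from 88.6 ± 25.1 to 3236 ± 323 CPM (log2 fold change 5.19, SE 0.26, adjusted p = 1.19e-05). *Pir*, an iron-binding nuclear protein, rose 31.7-fold and the quinone reductase *Nqo1* 26.9-fold, the latter from 6.25 ± 1.79 to 169 ± 15.7 CPM. Sulfiredoxin (*Srxn1*) rose 17.5-fold, *Gclm*, a subunit of the enzyme that starts glutathione synthesis, 13.2-fold, the thioredoxin reductase *Txnrd1* 10.4-fold and the aldehyde oxidase *Aox1* 7.95-fold. *Calr3*, a member of none of the lists, rose 10.4-fold from 6.93 ± 2.10 to 71.55 ± 5.21 CPM (edgeR adjusted p = 5.62e-05). The 4 genes that fell were the zinc importer *Slc39a10* (log2 fold change -1.23), the p38-activating kinase *Map2k6* (-1.18), *Stox2* (-1.06) and the death ligand *Tnfsf10* (-0.89). The number called was 365 with DESeq2 (295 higher, 70 lower) and 259 without citrate buffer replicate 1 (221 higher, 38 lower), the latter including all 81, and it fell to between 46 and 51 when citrate buffer replicate 2 or 3 or any iron citrate library was left out. *Slc39a10* missed the threshold without iron citrate replicate 1, 2 or 4 (adjusted p up to 0.0644), *Stox2* without citrate buffer replicate 2 or any iron citrate library (up to 0.078) and *Tnfsf10* without any 1 of citrate buffer replicates 2 to 4 or iron citrate replicates 2 to 4 (up to 0.121). With the replicate block none of the 4 that fell passed (adjusted p = 0.0723 for *Slc39a10*, 0.0928 for *Map2k6*, 0.0942 for *Stox2* and 0.0674 for *Tnfsf10*).

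**Figure D2:**
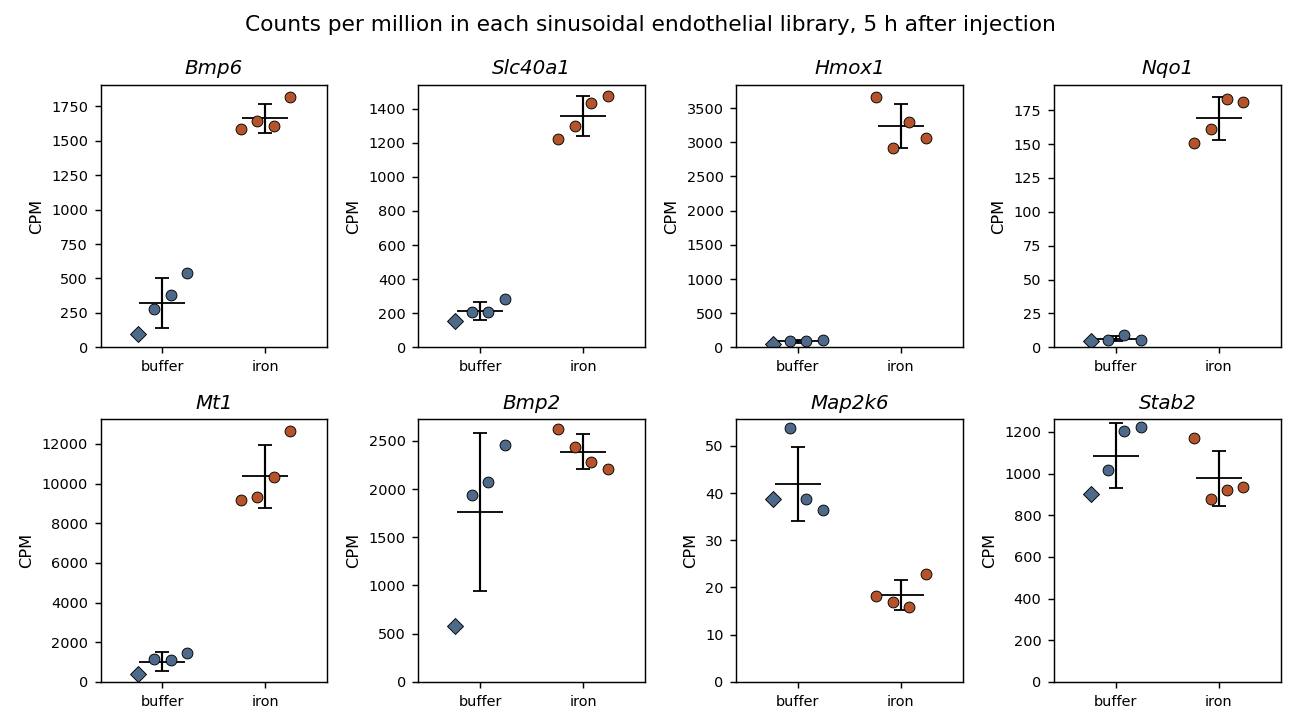
Points give the CPM of 8 genes in each library (y axes from 0), with the mean and SD of each group of 4 in black, and the diamond marks citrate buffer replicate 1. *Bmp6*, *Slc40a1*, *Hmox1*, *Nqo1* and *Mt1* were higher and *Map2k6* lower in every iron citrate library than in any buffer library, whereas *Bmp2* and *Stab2* overlapped.

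Of 29 measured targets of NRF2, the factor that drives genes against oxidative stress, 16 rose, none fell and 13 did not pass, and 22 rose when adjusted over the list alone. Their median log2 fold change was 1.36, and the list was higher by camera with an adjusted p of 7.07e-31 (adjusted p = 0.049 with an estimated correlation). Besides the genes above, the stress protein *Osgin1* rose 7.09-fold (adjusted p = 0.00229). All 6 NRF2 targets named here kept their call in every alternative. The mRNA of NRF2 itself, *Nfe2l2*, was at 186 ± 16.1 CPM after buffer and 232 ± 47.9 CPM after iron (adjusted p = 0.333).

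Among 20 measured genes of iron handling, 2 rose and 18 did not pass, and 4 rose when adjusted over the list alone. The iron exporter ferroportin, *Slc40a1*, rose 6.39-fold from 212 ± 53.3 to 1356 ± 117 CPM (log2 fold change 2.68, SE 0.20, adjusted p = 0.000213), and the haem transporter *Slc48a1* rose 4.96-fold (adjusted p = 0.00676). *Tfrc*, the transferrin receptor whose mRNA is degraded in iron-replete cells, was low in both groups, at 6.01 ± 0.65 and 7.58 ± 0.17 CPM (adjusted p = 0.491). The list was higher by camera (adjusted p = 0.000519), a call lost in 4 of 21 alternatives (adjusted p = 0.762 with an estimated correlation). *Mt1*, a metallothionein that binds zinc and copper, rose 10.1-fold from 1025 ± 467 to 10360 ± 1590 CPM (adjusted p = 0.0032), while *Slc39a10* fell. Of 8 measured genes of metallothioneins and zinc transport these were the only called ones, 3 rose and 1 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.147).

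Within BMP-SMAD signalling, *Bmp6* was the only one of 24 measured genes called, and 3 rose when adjusted over the list alone. The list was higher by camera (adjusted p = 0.0316, and adjusted p = 0.783 with an estimated correlation), but not in 5 of 21 alternatives, 1 of them without citrate buffer replicate 1 (adjusted p = 0.0818). For the kinases of the study's question, 1 of 30 measured MAPK kinases and phosphatases fell, *Map2k6*, from 41.9 ± 7.92 to 18.4 ± 3.12 CPM (SE 0.18, adjusted p = 0.0168), and none rose. Adjusted over the list alone, 1 rose and 1 fell, and the list did not pass (adjusted p = 0.353). The member that rose was *Map2k3*, also a kinase that activates p38, which is outside the naming rule. Its log2 fold change was 1.71, with an edgeR adjusted p of 0.0789 over all genes and 0.00754 over the list. *Map2k6* missed the threshold without citrate buffer replicate 2 or 3 or iron citrate replicate 1, 2 or 3 (adjusted p up to 0.103) and with the replicate block. The p38 alpha gene *Mapk14* was at 87.2 ± 27.4 and 99.8 ± 8.14 CPM (adjusted p = 0.64) and p38 beta, *Mapk11*, at 49.6 ± 3.54 and 51.7 ± 3.83 CPM (adjusted p = 0.813). No ETS factor of 15 was called, over all genes or when adjusted over the list alone (list adjusted p = 0.354), and *Ets1* was at 684 ± 226 CPM after buffer and 771 ± 82.8 CPM after iron (log2 fold change 0.17, SE 0.23, adjusted p = 0.707). Nor was any of 25 immediate-early genes of the AP-1 group, in which *Jun* stood at 935 ± 42.0 and 1094 ± 154 CPM, though 3 rose when adjusted over the list alone (list adjusted p = 0.309). These values are mRNA levels, which leave the activity of p38 and of ETS1 unmeasured.

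**Figure D3:**
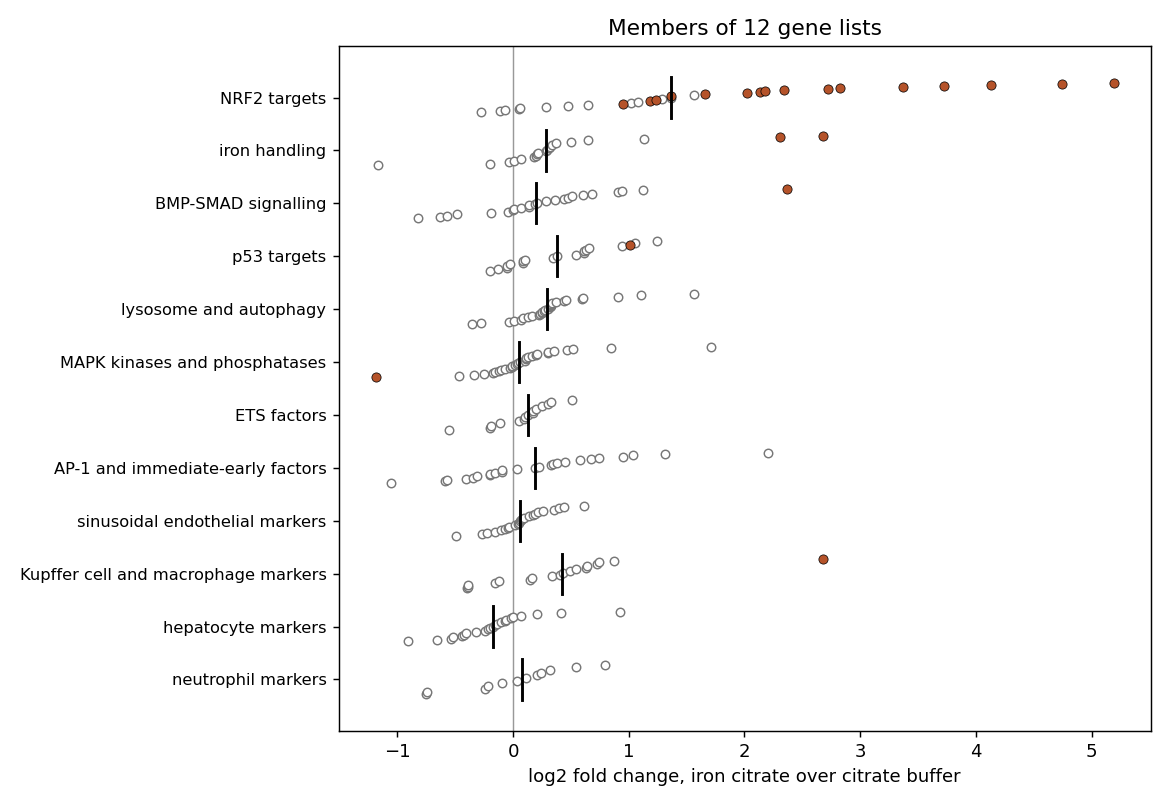
Each point is a measured member of a gene list at its log2 fold change (x axis), filled where it was called over all genes at an adjusted p under 0.05, and the black bar is the list's median. The NRF2 targets had a median of 1.36 and 16 called members, and no other list shown had more than 2.

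Other lists were called by camera with few called members, and each call was lost with an estimated correlation. Of 19 p53 targets, *Cdkn1a*, the inhibitor of cyclin-dependent kinases, rose 2.01-fold (adjusted p = 0.012), 2 rose when adjusted over the list alone, and the list was higher (adjusted p = 0.00151, and adjusted p = 0.208 with an estimated correlation). Among 20 hypoxia and glycolysis genes *Aldoa* rose 2.31-fold, 2 rose when adjusted over the list alone, and the list was higher (adjusted p = 0.0356). The lysosome and autophagy list (adjusted p = 0.000245), TGF-beta and extracellular matrix genes (0.0128) and heat-shock proteins (0.0356) were higher with no called member, and adjusted over the list alone 1, 0 and 0 rose. The 64 respiratory chain subunits were lower as a list (adjusted p = 0.0363), with a median log2 fold change of -0.09 and none called. For these 5 lists the adjusted p with an estimated correlation was 0.783, or 0.834 for the respiratory chain. Without citrate buffer replicate 1 the hypoxia, TGF-beta and heat-shock lists did not pass (adjusted p = 0.186, 0.105 and 0.0667). The respiratory chain did not pass without citrate buffer replicate 3 or 4 or iron citrate replicate 1, 2 or 4 (adjusted p up to 0.509). It was lower by camera without citrate buffer replicate 1 (median -0.161, adjusted p = 0.00159) and without citrate buffer replicates 1 and 2 (-0.227, 1.53e-08). With the silent-family covariate it was lower too (-0.239, 9.23e-09). With an estimated correlation and without citrate buffer replicate 1 its adjusted p was 0.861. Of 21 alternatives the p53 list lost its call in 1, the lysosome list in 4, the TGF-beta list in 6, the hypoxia list in 8 and the heat-shock and respiratory chain lists in 9 each. *Cdkn1a* missed the threshold without citrate buffer replicate 3 or iron citrate replicate 3 or 4 (adjusted p up to 0.0567) and with upper-quartile factors (0.0624), library totals (0.0569) or the replicate block (0.0928). *Aldoa* missed it without citrate buffer replicate 2 or any iron citrate library (up to 0.0928).

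Sterol synthesis had 1 called gene of 20, *Insig1*, the sterol sensor of the endoplasmic reticulum, which rose 1.85-fold (adjusted p = 0.013, and 1 rose when adjusted over the list alone), and the list did not pass (adjusted p = 0.305). *Insig1* missed the threshold without citrate buffer replicate 2 or any iron citrate library (adjusted p up to 0.0701) and with the replicate block (0.0939). No member was called, over all genes or when adjusted over the list alone, among NF-kB and inflammatory genes, interferon-stimulated genes, the ER and integrated stress response, ferroptosis genes, the cell cycle, Notch and angiocrine genes and cytosolic ribosomal proteins. Their adjusted p-values by camera were 0.475, 0.414, 0.439, 0.0772, 0.504, 0.0657 and 0.536. In the alternatives the Notch list was called higher in 8 of 21 (adjusted p down to 0.0292), the ferroptosis list higher in 3 (down to 0.0305) and the ER stress list lower in 1 (0.0421). With an estimated correlation in all 8 libraries their adjusted p-values were 0.783, 0.783 and 0.834. The median, the mean and the direction of the test differed in sign for the NF-kB, ER stress, cell cycle and ribosomal lists and for those of monocytes, cholangiocytes and platelets, none of which passed.

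Markers of cell types were measured to see what the sort held. Of 24 sinusoidal endothelial markers none was called and the median log2 fold change was 0.06 (adjusted p = 0.439). *Mcam*, which encodes the CD146 used in the sort, was at 253 ± 34.8 and 179 ± 11.3 CPM (log2 fold change -0.50, adjusted p = 0.239). It was called lower in 7 of 18 alternatives, among them DESeq2 (adjusted p = 0.00319), limma-voom (0.00813), library totals (0.0452), upper-quartile factors (0.0464) and the fit without citrate buffer replicate 1 (-0.59, adjusted p = 0.0135). *Ptprc*, which encodes CD45, stood at 382 CPM in citrate buffer replicate 1 and between 135 and 208 CPM in the other libraries. Ferroportin was the only called gene of 18 Kupffer cell and macrophage markers, over all genes and over the list alone, and the list did not pass (median log2 fold change 0.42, adjusted p = 0.103). The list was higher in 6 of 21 alternatives, with DESeq2 (adjusted p = 0.0253), library totals (0.0461), upper-quartile factors (0.0441) and the replicate block (0.0441) and without iron citrate replicate 1 (0.0382) or 4 (0.0256). With an estimated correlation in all 8 libraries its adjusted p was 0.83. The list did not pass by camera without citrate buffer replicate 1 (median 0.142, adjusted p = 0.341) or with the silent-family covariate (-0.049, 0.991). Its most abundant other member, the lysozyme *Lyz2*, was at 655 ± 214 and 499 ± 69.3 CPM (adjusted p = 0.356). *Clec9a*, a dendritic cell lectin, rose 1.69-fold from 197 ± 22.1 to 333 ± 4.41 CPM (adjusted p = 0.0221) and was the only called one of 14 monocyte and dendritic cell markers, also when adjusted over the list alone (list adjusted p = 0.75). It missed the threshold without citrate buffer replicate 2 or 3 or any iron citrate library (adjusted p up to 0.13), and with the replicate block (0.125) or upper-quartile factors (0.0647). Continuous endothelial markers were higher as a list (adjusted p = 0.0356, and adjusted p = 0.783 with an estimated correlation) with 3 rising only when adjusted over the list alone. That call was lost in 8 of 21 alternatives, 1 of them without citrate buffer replicate 1 (adjusted p = 0.186).

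No member was called over all genes in the lists of hepatocytes (adjusted p = 0.14), neutrophils (0.62), T and NK cells (0.439), B and plasma cells (0.443), stellate cells (0.0657), cholangiocytes (0.661), lymphatic endothelium (0.414), erythroid cells (0.901) or platelets (0.905). Adjusted over the list alone, 1 erythroid gene rose, 1 fell, and no other member of these lists was called. The hepatocyte list was lower without citrate buffer replicate 1 (adjusted p = 0.0123) or iron citrate replicate 1 (2.01e-05) and in 4 of 21 alternatives altogether. With an estimated correlation its adjusted p was 0.861 without citrate buffer replicate 1 and 0.834 in all 8 libraries. The stellate list was higher in 7, among them those without citrate buffer replicate 2 or 3 or iron citrate replicate 1 (adjusted p = 0.0258, 0.00705 and 0.0165), and the neutrophil list in 4. With an estimated correlation in all 8 libraries their adjusted p-values were 0.83 and 0.838. Hepatocyte RNA was present in both groups, with *Alb* at 458 ± 152 CPM after buffer and 319 ± 107 CPM after iron (adjusted p = 0.345). In citrate buffer replicate 1 the granzyme *Gzma* stood at 1261 CPM against 265 to 384 CPM in the other buffer libraries, while the B cell marker *Cd79b* was lower than in any other library, at 18.1 CPM.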

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

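The tests of the silent families' intron structure and of their even gain, and those of the markers of sinusoidal endothelial and Kupffer cells were chosen only after the results they bear on were seen. The share of targets with a signal, in intronless families and in split ones, and Y-linked targets had been meant for the first of these. Neither could decide. Most intronless targets had a signal in every library, and the mice were female per the labels, so their DNA would not carry the 13 Y-linked targets.

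A sample far from the other 3 of its group was found in 17 of 186 groups of values examined. A rate of 1 in 20 gives about 9.3, which holds only for independent and normally spread values. The groups came from the same 8 libraries, so this is not a test against chance. Of the 17, 7 were citrate buffer replicate 1. In that library *Gzma* was at 1261 CPM, *Lcn2* at 186.8, *S100a9* at 135.5, *Acsl4* at 85.42, *Mdm2* at 75.33 and *Mki67* at 54.38 CPM, all above the other buffer libraries, and *Osgin1* was below them at 11.52 CPM. In citrate buffer replicate 2, *Map2k6* was high at 53.7 CPM, and *Hspa1b* at 32.15 and *Ndufv3* at 63.3 CPM were low. The 10 most abundant targets took 11.32% of the counts in citrate buffer replicate 3, below the other buffer libraries. Among iron citrate libraries *Alb* was high in replicate 1 (478.7 CPM), *Slc48a1* high (291.0 CPM) and *Osgin1* low (150.0 CPM) in replicate 2, *Ets1* (894.7 CPM) and *Aldoa* (63.66 CPM) high in replicate 3, and *Rpl32l* high in replicate 4 (8.084 CPM).

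Citrate buffer replicate 1 also carried the most counts on gene families silent in liver. RNA of a tissue that expresses these families would raise olfactory receptors, taste receptors and keratin-associated proteins unequally, but their summed CPM stood 5.22, 5.14 and 5.02 times above the median of the other libraries, a lowest-to-highest ratio of 0.961. Over the median of the other 7 libraries, the mean CPM per target was higher in that library by 0.0406 in families split by introns and by 15.2 in intronless ones, a ratio of 0.0027, so genomic DNA amplified with the cDNA remains a candidate explanation for these counts. It leaves open the high *Gzma*, *Lcn2* and *S100a9* in that library, which have introns. No other biological explanation for this library was tested.

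The spread that citrate buffer replicate 1 adds may have limited the number of genes called. Without it 3.2 times as many were called, 259 against 81, although 1 library fewer was tested. None of the other 34 splits of the 8 libraries into 4 and 4 gave a call by edgeR, against 81 in the real one. The real split is 1 of 35, the smallest share such a test can give, so chance was not excluded. The other splits also place iron and buffer libraries in the same group, which widens the spread of genes that differ between them. At an unadjusted p under 0.05 the splits were less separate, with 2127 genes in the real one and up to 3799 in another. Among the 7 libraries without citrate buffer replicate 1, the real split gave 259 calls and the highest of the other 34 gave 4, so 1 split of 35 reached that count.

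The splits did not set the number of gene lists called by camera apart. It was 10 in the real split, 10 of the 35 splits reached it, and another split gave 15. Splits that mix the treatments unequally, that one among them, keep part of the iron contrast and cannot stand for chance. Splits with equal numbers of both treatments in each group called 4 to 10 lists. Without citrate buffer replicate 1 the number in the real split was 7, which 16 of 35 splits reached, with up to 13 in another. The NRF2 list was lower in adjusted p in the real split (7.07e-31) than in any other (3.78e-10 at the lowest). That lowest value came from an unequally mixed split, and the lowest among equally mixed ones of the 8 libraries was 0.297. Lists that call no or few single genes may thus reflect the structure among the libraries.

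The rises of *Bmp6*, *Slc40a1* and *Hmox1* could come from a different mix of cells. More sinusoidal endothelial RNA in the iron citrate libraries would raise the other markers by about as much as *Bmp6*. The median of the 24 was 0.06 with an SD of 0.24, against 2.36 for *Bmp6*. In both groups the cells were sorted for such markers, which leaves their share little room to rise. The markers could hardly have matched *Bmp6*, so this comparison does not decide the question. More Kupffer cell RNA would raise the Kupffer cell markers by about as much as *Slc40a1*, but the median of the other 17 was 0.41 with an SD of 0.43, against 2.68. *Hmox1* was not set against these markers. Of the 18 with *Slc40a1*, 13 had a positive log2 fold change. The abundant *Lyz2* went the other way (-0.39), but its highest value, 952 CPM, was in citrate buffer replicate 1. The sort kept CD45-dim cells, so it does not exclude Kupffer cell RNA. A smaller gain of Kupffer cell RNA stays open, since their list, which includes *Slc40a1*, was called higher in 6 of 21 alternatives. All 6 kept citrate buffer replicate 1. Without that library the median of the list was 0.142 (camera adjusted p = 0.341), and with the silent-family covariate it was -0.049 (0.991). A response to iron within the sorted cells, the difference named by the design, remains as a hypothesis for these genes.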

How the results depend on the processing

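The fit without citrate buffer replicates 1 and 2 and the fit with the silent-family signal as a covariate were chosen only after the data were seen. All 20 named genes called by edgeR other than *Bmp6* kept their direction in their 360 refits, and 312 of those passed the threshold. Among all 83 named genes besides *Bmp6*, 125 of 1493 refits, over 32 genes, crossed 0, none of them for a called gene. The log2 fold change of *Bmp6* lay between 1.86 and 2.72 in all alternatives. It missed the threshold with the replicate block (2.58, adjusted p = 0.0517) and without citrate buffer replicate 2 (0.219) or 3 (0.13) or iron citrate replicate 1 (0.138), 2 (0.13), 3 (0.144) or 4 (0.154), with 1 sample fewer in each of the last 6.

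Leaving out 1 library gave 46 to 259 genes called, 45 to 221 higher, 0 to 38 lower, 44 to 102 changed at least 2-fold, 7 to 13 gene lists and a *Bmp6* change of 2.06 to 2.72. The highest count came without citrate buffer replicate 1 (259), and the calls numbered 48, 50, 46, 46, 51 and 49 without citrate buffer replicates 2 and 3 and iron citrate replicates 1 to 4. DESeq2 called 365 genes (295 higher, 70 lower, 131 at least 2-fold) and limma-voom 289 (246, 43 and 105), with a weight of 0.119 for citrate buffer replicate 1. Without citrate buffer replicates 1 and 2 there were 281 (200, 81 and 100), and with the covariate 327 (233, 94 and 107) and 5 lists. The share of calls that were higher was 95.1% in the reported test, 80.8% with DESeq2, 71.2% without both buffer libraries and 71.3% with the covariate. Of 34 lists, camera with an estimated correlation called 1 and fry 2. Apart from the spread set by citrate buffer replicate 1, the cause was not tested.

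The labels do not say that the replicate numbers pair the libraries. Same-numbered ones deviated from their group means with correlations of 0, 0.176, 0.609 and -0.315, and not every library went best with its own number. The value for replicate 3, 0.609, was the highest of any pair. The buffer mean includes citrate buffer replicate 1, which stood apart and weighs on every buffer deviation, so this check cannot exclude pairing. With the replicate block 43 genes were called, 43 higher and 0 lower, and 1558 at an unadjusted p under 0.05.

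The neutrophil gene *Lcn2* reversed, from an uncalled -0.24 to a called 0.76 without citrate buffer replicate 1 and 0.95 without citrate buffer replicates 1 and 2, with a range of -0.50 to 0.76 over single libraries left out. The sinusoidal endothelial list turned from uncalled higher to lower by camera without both (adjusted p = 0.0221). Without citrate buffer replicate 1 alone its median log2 fold change was -0.06, uncalled (adjusted p = 0.304). With an estimated correlation in all 8 libraries the adjusted p of this list was 0.834. Upper-quartile factors and library totals moved the median log2 fold change of all genes to -0.12 and -0.11. In the simulation a 2-fold change was called in 32 of 100 genes with a mean CPM of at least 5, so a gene not called is not shown to be unchanged. The simulation held no library that stood apart, so this share may differ in the real data.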

Other observations

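The genes of these observations were picked after their values were seen, while the fit without citrate buffer replicate 1 and the lists had been fixed beforehand. Of the 81 called genes, 55 were in none of the fixed lists, 53 of them higher and 2 lower. The aldo-keto reductase *Akr1b8* rose 6.34-fold from 515 ± 59.6 to 3263 ± 150 CPM (adjusted p = 1.77e-05), the microsomal glutathione transferase *Mgst1* 4.28-fold and catalase, *Cat*, 2.59-fold from 78.9 ± 7.60 to 204 ± 24.9 CPM. *Mafg*, a small MAF protein that binds DNA with NRF2, rose 1.95-fold (adjusted p = 0.00894). The nuclear receptor *Pparg* rose 3.59-fold from 10.2 ± 2.49 to 36.3 ± 2.88 CPM (adjusted p = 0.0018). *Mlkl*, the effector of necroptosis, rose 1.98-fold (adjusted p = 0.00355). The AMP deaminase *Ampd3* rose 4.32-fold and the laminin-binding integrin *Itga6* 2.31-fold, from 70.7 ± 7.12 to 164 ± 11.6 CPM.

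Without citrate buffer replicate 1, 5 of 12 neutrophil markers were higher after iron citrate, and 7 when adjusted over the list alone. *S100a8* stood at 23.2 ± 1.80 CPM in citrate buffer replicates 2 to 4 and at 39.9 ± 6.31 CPM after iron (adjusted p = 0.0182), with 115.8 CPM in citrate buffer replicate 1. *Csf3r*, the receptor for the granulocyte growth factor, had a log2 fold change of 1.19 (adjusted p = 0.00425) and the cytokine *Il1b* one of 1.33 (adjusted p = 0.000618). In all 8 libraries neither passed (0.547 and 0.392, adjusted p = 0.468 and 0.694), and citrate buffer replicate 1, at 75.5 and 133.5 CPM, lay above the iron means of 53.02 and 71.98 CPM. *S100a8* did not pass there either (-0.22, adjusted p = 0.841). Without citrate buffer replicate 1 the neutrophil list was higher by camera (adjusted p = 0.0016, and adjusted p = 0.36 with an estimated correlation). In the same fit *Map2k3*, a kinase that activates p38, was higher with a log2 fold change of 1.48 (adjusted p = 0.00213), while in all 8 libraries it did not pass (1.71, adjusted p = 0.0789), and *Map2k6* fell in both. *Fbxl5*, the iron sensor that degrades IRP2, and the mitochondrial iron importer *Slc25a37* were higher with log2 fold changes of 0.54 and 0.95 (adjusted p = 0.0252 and 0.00213), and in all 8 libraries neither passed (0.503 and 1.13, adjusted p = 0.125 and 0.0836).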
